A study of Mus musculus with 12 samples.

How the data were processed

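Gene expression was measured on Affymetrix mouse whole-transcript arrays in 12 samples of sorted epidermal cells, 3 in each of 4 groups: clock-positive and clock-negative bulge cells, and basal interfollicular epidermis cells of wild-type mice and of mice with an epidermal knockout of Bmal1. Per the labels' protocols, total RNA was amplified with a whole transcriptome amplification kit before labelling. The deposited values are log2 intensities made with RMA, per the submitters' processing notes; its version and settings were not analysed here. The values themselves place them on a log2 scale. The bulge columns are filled for 34760 probe sets, the epidermis columns for 28853 and both for 28101, so the 2 sets appear to have been normalized separately, and no level of one set was tested against the other. An array has no read depth: the number of arrays limits the precision. No 2 columns were identical and all 12 were used.

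Probe sets were joined to genes with the symbols given for the series matrix. Of 35512 probe sets, 21789 carry 1 symbol (19938 symbols), 1621 carry several and 12102 have no listed gene; the last 2 kinds were left out of the gene tests. The Entrez identifiers of 21698 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols; no coordinates are given. For the 999 symbols with more than 1 probe set, the probe set measured on all 12 arrays was preferred and then the one with the highest mean; the preference was added to the written rule after the gaps between the sets were seen. In each comparison the 30% of genes with the lowest mean over its arrays were left out as dim, which left 13956 genes.

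Each comparison was fitted with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of an adjusted p under 0.05; the moderated tests are two-sided. The bulge comparison (clock-positive minus clock-negative) and the epidermis comparison (KO minus wild type) each used their own 6 arrays. The third fitted all 12 arrays with 4 group means and tested the difference (clock-positive minus clock-negative) minus (wild type minus KO). As the sets appear to have been normalized separately, this is a difference of changes within sets that also differ in tissue, age and pool size and, by the levels of sex-linked genes, probably in sex. Values after ± are standard errors of the fit unless marked SD. Overlaps of calls were set beside the number expected at random with Fisher's exact test, over the 13100 genes tested in both.

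The lists were written before the data were examined, as were the tests, thresholds, the rule for naming genes and all alternatives but those listed below as later. There were 23 gene lists: clock repressors and E-box driven outputs, clock activators and RORE driven genes, bulge stem cell genes, hair germ and activated progenitor genes, Wnt target genes, Wnt inhibitors and antagonists, TGF-beta pathway and targets, BMP pathway and targets, Notch pathway, cell cycle, CDK inhibitors and p53 targets, epidermal differentiation, basal keratinocyte and hemidesmosome, antioxidant and NRF2 targets, interferon response, cytokines and skin inflammation, immediate early and dissociation response, glucocorticoid responsive genes, cholesterol synthesis, oxidative phosphorylation, cytosolic ribosomal proteins, DNA repair, and cytosolic and ER stress chaperones. The 18 marker lists were melanocyte, dermal fibroblast, T cell, Langerhans and other myeloid cell, mast cell, endothelium, skeletal muscle, adipocyte, red blood cell, sebocyte, inner root sheath, hair shaft, upper hair follicle, interfollicular basal cell, Schwann cell, smooth muscle and pericyte, male (Y-linked) and female (X inactivation). Lists share some genes, but 0 of the 10 T cell genes on the array stand in another list. Listed genes with no probe set of their own symbol, such as Npas2 and Cdkn1a, were not analysed here. Lists with at least 3 genes tested were run with camera at a preset correlation of 0.01 between genes. The p-values were adjusted over the lists of a comparison. The lists were also run in camera with an estimated correlation, and in fry. With an estimated correlation camera also draws on the few residual degrees of freedom of the arrays, which lowers its power. A list that misses there is therefore not shown to owe its preset result to correlated genes. Counts of members past the threshold are given over all genes and, where they differ, adjusted over the list alone.

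The genes named were those of the 2 clock lists, in each direction up to 10 genes with the largest change among those past the threshold whose 3 values in one group all lay above the 3 in the other (10% of splits of 3 against 3 do so by chance), and up to 4 members of each list with the smallest p; unnamed models and accession symbols were passed over. For the third comparison they were the genes called in both contrasts and the 5 with the largest difference. Members that went against the rest of their list, and the values per array of H2-Ab1, were named after their values were seen. Of genes with several probe sets tested, 48 of 695 in the bulge and 0 of 760 in epidermis had probe sets called in opposite directions.

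The fits were tested on simulated data with the real means and spread and 200 changed genes among 13956. In the bulge comparison 85.1% of genes changed 1.5-fold were recovered, and 100% of those changed 2-fold or 4-fold. In epidermis the shares were 32.8%, 68.7% and 95.5%, and for the difference 38.8%, 73.1% and 98.5%. False calls made up 3.06%, 5.07% and 3.45% of calls, and 0 calls were made with no gene changed. Each simulated gene was drawn independently of the others. In the real arrays 50.1% of the variance within groups in the bulge and 69.0% in epidermis lay on a single axis. The simulated rates therefore need not hold for the real arrays.

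Alternatives planned beforehand were a fold of at least 1.5, an adjusted p under 0.10, no filter or a 50% filter on dim genes, the mean of all probe sets or each probe set tested, quantile normalization over 12 arrays, median centring, an intensity trend, a robust trend, array weights, a block for replicate number, all 12 arrays in 1 fit, and leaving out each array in turn. Cyclic loess, the SD of each array as a covariate in epidermis and median centring of the lists were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.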

Results

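The series measured gene expression in epidermal stem cells sorted from mouse dorsal skin, on 12 whole-transcript microarrays with 3 arrays in each of 4 groups. One set of 6 arrays holds bulge cells, the stem cells of the hair follicle, taken at 18 to 19 days of age from mice that carry Per1-Venus, a fluorescent reporter of the clock gene Per1. These cells were sorted for bright alpha6 integrin and for CD34, and then into clock-positive cells with bright Venus and clock-negative cells with dim Venus, with about 20 mice pooled per sample. The sample labels of the clock-negative cells also state the Venus-high gate, so the groups here follow the sample titles and the series design. The other set of 6 arrays holds basal cells of the interfollicular epidermis from mice 1 year old, either wild type or with an epidermal knockout (KO) of Bmal1, the clock activator whose gene symbol is Arntl, with 5 mice per sample. The values are log2 intensities, with array medians from 6.82 to 7.01 in the bulge set and higher ones in the epidermis set. Different probe sets carry values in the 2 sets, which appear to have been processed apart, so levels are tested only within a set. Those of sex-linked genes are described in both sets without a test. The number of arrays limits the precision. The time of day of collection was not analysed here.

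The first comparison asks how bulge stem cells with a bright Per1 reporter differ from those with a dim one. Clock-positive cells had higher values of genes that mark the bulge stem cell and of the TGF-beta and BMP pathways, and clock-negative cells had higher values of genes of differentiated epidermis, the hair shaft, the inner root sheath and T cells. As lists these stood apart from other genes with a preset correlation between genes and none did with an estimated one, as given below for each. The highest fold was that of Scrg1, 5.08-fold higher in clock-positive cells (log2 change 2.34 ± 0.08 SE, n = 3 per group, adjusted p = 7.20e-08). Angptl7, a secreted angiopoietin-like protein, was 4.69-fold higher, and the keratin Krt24 was 3.82-fold higher. Camk4, a calcium-dependent kinase, Pdzrn4, Mia, the kinase Dapk2, Id2, a target of BMP signals, S100a4 and Hpgd, which breaks down prostaglandins, followed with log2 changes from 1.93 down to 1.56. The largest falls were in hair keratin-associated proteins and late cornified envelope proteins: Krtap6-3 fell by 2.09 ± 0.20 on the log2 scale, with Krtap6-2 at −1.87, Krtap6-5 and Krtap8-1 at −1.86, Lce1b at −1.89, Lce1c at −1.79 and Lce1a1 at −1.66. Genes of these 2 families are alike in sequence, so probes may read more than one member. Cd3g, a chain of the T cell receptor complex, fell by 1.69, Alas2, an enzyme of haem synthesis in red blood cells, fell by 1.62 and Wfdc21 fell by 1.58. Each of these 20 genes kept its call without any 1 array and under each scaling tried.

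Of 13956 genes tested, 8866 passed the threshold of an adjusted p under 0.05 in limma, 6311 higher and 2555 lower in clock-positive cells. The balance depended on the filter on dim genes: with no filter 6285 were higher and 5564 lower, and with the lowest 50% of genes left out 5947 and 740. Most changes were small: 1008 genes also had a fold of at least 1.5, 714 higher and 294 lower. The median change of all genes was 0.15 on the log2 scale and the list medians are therefore given relative to it. After median centring 10283 genes passed (8928 higher, 1355 lower), after quantile normalization 5443 (3561 higher, 1882 lower) and after cyclic loess 5739 (3531 higher, 2208 lower). With the same sign under the deposited values and these 3 scalings, 4147 genes passed, 3109 higher and 1038 lower. A fit that took the spread from all 12 arrays called 5301.

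Bulge stem cell genes stood highest among the lists fixed beforehand, with a median change 0.648 above that of all genes. Of 22 tested, 20 rose and 0 fell, though under quantile normalization and cyclic loess 1 member, Itga6, fell (camera adjusted p = 1.74e-07, and adjusted p = 0.304 with an estimated correlation). With adjustment over the list alone, 21 rose. They included Cd34 at 1.45 ± 0.06, Lgr5, a receptor for R-spondins on stem cells, at 1.34 ± 0.06, the secreted factor Fgf18 at 1.23 ± 0.07 and Grem1, a BMP antagonist, at 1.17 ± 0.06. CD34 protein was a marker of the sort itself. In the TGF-beta list 19 of 24 rose, Tgfbr3 fell under quantile normalization and cyclic loess, and the list as a whole was higher than other genes (adjusted p = 1.92e-04, and adjusted p = 0.357 with an estimated correlation). Ltbp2, a matrix protein of the latent TGF-beta binding family, changed by 1.17 ± 0.06, Ccn2, a TGF-beta target, by 1.15 ± 0.07, Thbs1 by 0.97 ± 0.06 and Fst, an antagonist of activins, by 0.93 ± 0.06. In the BMP list 16 of 20 rose and Bmp4 fell, except after median centring (adjusted p = 0.00101, and adjusted p = 0.242 with an estimated correlation). The BMP targets Id2, Id1 and Id3 rose by 1.57 ± 0.07, 0.93 ± 0.07 and 0.81 ± 0.07, beside Grem1. Grem1 and Bmp6 stand in both the bulge and BMP lists, and Ccn2 in both the bulge and TGF-beta lists. The results of these lists are therefore not fully separate. Cell cycle genes also stood above other genes, with 27 of 37 higher and Ccne1 lower as deposited (adjusted p = 0.00541, and adjusted p = 0.665 with an estimated correlation), but missed the threshold with the lowest 50% of genes left out (adjusted p = 0.131). Examples are Ccna2 at 0.61 ± 0.06 and the mitotic motor Kif11 at 0.70 ± 0.08, while the replication factors Mcm2, Mcm5 and Mcm6 were called lower under quantile normalization and cyclic loess. Cholesterol synthesis genes passed as deposited, 14 of 16 higher (4 after quantile normalization, and 3 higher and 1 lower after cyclic loess; adjusted p = 0.0296, and adjusted p = 0.591 with an estimated correlation), but not after quantile normalization (adjusted p = 0.202) or cyclic loess (adjusted p = 0.306), nor with the lowest 50% of genes left out (adjusted p = 0.212). Markers of endothelium also rose, 10 of 11, among them Cdh5 at 0.63 ± 0.07, Emcn at 0.56 ± 0.06 and Pecam1 at 0.56 ± 0.07 (adjusted p = 0.0222, and adjusted p = 0.242 with an estimated correlation). As a list they missed the threshold with the lowest 50% of genes left out (adjusted p = 0.136).

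Genes of terminally differentiated cells were higher in clock-negative cells. Of 30 epidermal differentiation genes 15 fell and 4 rose in clock-positive cells, while after median centring 9 rose (adjusted p = 6.41e-07, and adjusted p = 0.242 with an estimated correlation). Hornerin (Hrnr) fell by 1.20 ± 0.06 and loricrin (Lor), the main protein of the cornified envelope, fell by 1.17 ± 0.06, beside Lce1c and Lce1a1. Of 8 inner root sheath genes 7 fell and 0 rose, among them trichohyalin (Tchh) at −0.91 ± 0.07 and Krt72 at −0.74 ± 0.07 (adjusted p = 4.21e-06, and adjusted p = 0.124 with an estimated correlation). Of 16 hair shaft genes 11 fell, among them Krt33a at −0.80 ± 0.07 (adjusted p = 2.44e-05, and adjusted p = 0.242 with an estimated correlation). The 3 that rose, Hoxc13, Lef1 and Msx2, encode transcription factors rather than structural proteins.

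Markers of T cells, myeloid cells, melanocytes and skeletal muscle also stood higher as lists in clock-negative cells, unlike those of endothelium. All 9 T cell genes tested were lower in clock-positive cells, under each of the 4 scalings (adjusted p = 5.40e-10, and adjusted p = 0.0841 with an estimated correlation). Cd3g, with a mean of 9.19 ± 0.20 (SD, n = 3) in clock-negative cells, changed by −1.69 ± 0.10, Cd7 by −1.56 ± 0.09 and Cd3e by −1.18 ± 0.06. Of 10 markers of Langerhans and other myeloid cells 7 fell and 2 rose (adjusted p = 3.04e-04, and adjusted p = 0.242 with an estimated correlation), with H2-Ab1 at −0.74 ± 0.07 and Cd207, the marker of Langerhans cells, at −0.59 ± 0.07, while Fcgr3 and C1qc rose. The myeloid list missed the threshold with all 12 arrays in 1 fit (adjusted p = 0.0957). Melanocyte markers (1 of 7 higher, 5 lower, adjusted p = 0.0175, and adjusted p = 0.242 with an estimated correlation) and skeletal muscle markers (4 of 9 lower, adjusted p = 0.00832, and adjusted p = 0.438 with an estimated correlation) passed as deposited. Neither passed after quantile normalization (adjusted p = 0.132 for melanocyte and 0.183 for muscle) or cyclic loess (adjusted p = 0.178 and 0.219), and melanocyte markers also missed with the lowest 50% of genes left out (adjusted p = 0.0655). The pigment cell genes Mlana and Pmel changed by −0.75 ± 0.09 and −0.59 ± 0.07, while Mitf, the melanocyte transcription factor, rose by 1.24 ± 0.06. In all, 13 of 39 lists passed camera, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.0841 (0.0860 after cyclic loess); fry, which asks only whether a list moves one way, passed 32.

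Most clock genes differed little between the sorts. Per1, whose promoter drives the sorted reporter and so is no independent measure, rose by 0.51 ± 0.07 (adjusted p = 1.95e-04, higher in each of 3 arrays than in any clock-negative array). Of 14 clock repressors and outputs 6 rose and 0 fell as deposited, with Bhlhe41 at 1.11 ± 0.06, Cry2 at 0.54 ± 0.06, Tef and Ciart at 0.36 ± 0.06 and 0.36 ± 0.09, and Dbp at 0.28 ± 0.07. The list's median lay 0.0107 above that of all genes (camera adjusted p = 0.261), and with no filter on dim genes the list stood above other genes (camera adjusted p = 0.0247). With no filter 6285 genes were higher and 5564 lower, against 6311 and 2555 with it. That pass may therefore reflect the dim genes added. After cyclic loess, with the filter, the list did not stand apart (camera adjusted p = 0.859). After median centring 11 rose. Under quantile normalization and cyclic loess 3 were higher, Per1, Cry2 and Bhlhe41, and 3 lower: Per3 (−0.28 and −0.27), Wee1 (−0.31 and −0.30) and Hlf (−0.22 and −0.22). Nr1d1 was at 0.08 ± 0.06 (adjusted p = 0.298), Per2 at 0.12 ± 0.06 and Cry1 at 0.05 ± 0.06, none past the threshold. Among the activators and their targets Nfil3, a repressor of clock output genes, rose by 1.01 ± 0.09 and Clock by 0.36 ± 0.09, and 3 of 6 passed in all (camera adjusted p = 0.486). Arntl was 0.16 ± 0.07 higher (adjusted p = 0.0470), and its sign turned under quantile normalization and cyclic loess.

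**Figure D1:**
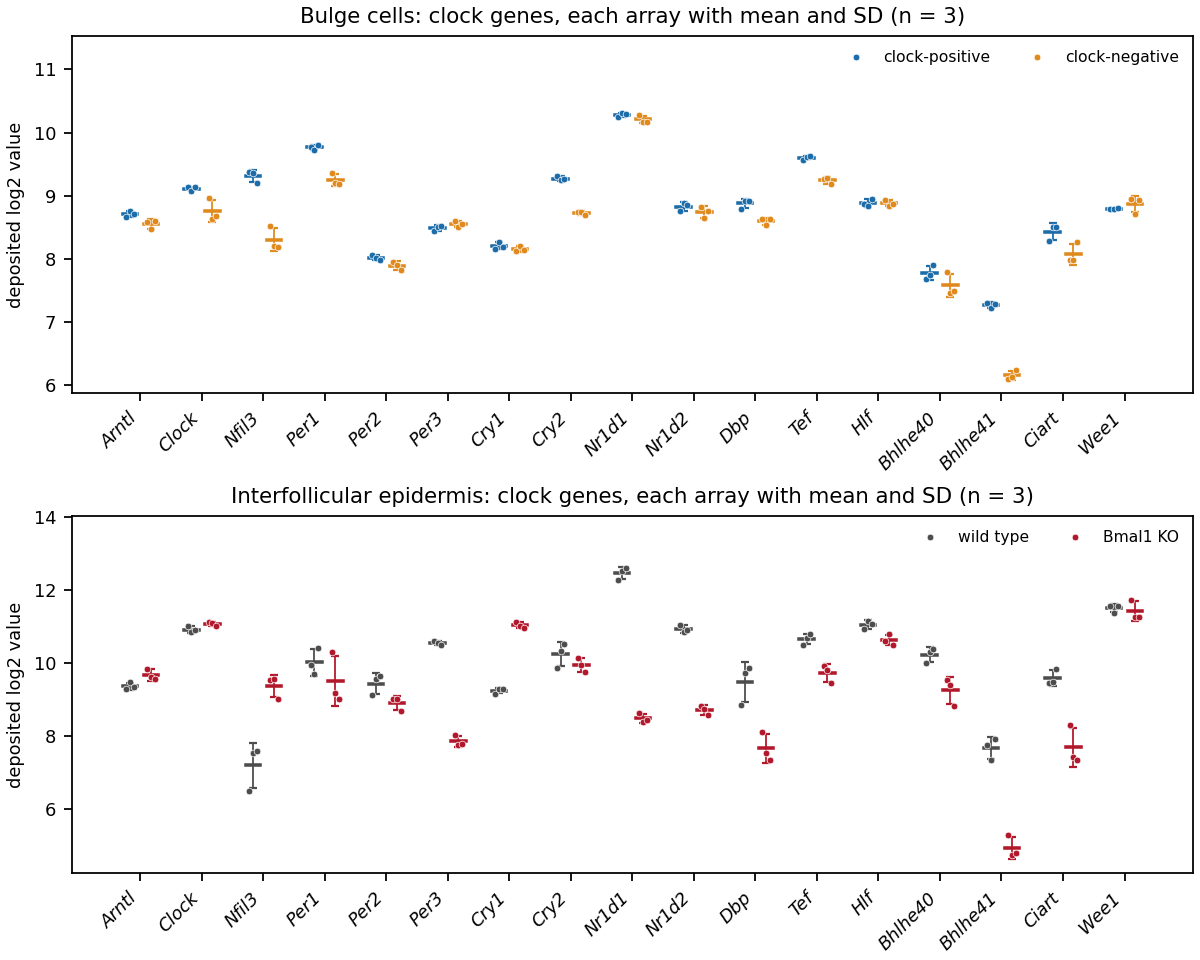
Deposited log2 values of 17 clock genes in each array (points), with the mean and SD of the 3 arrays per group (bars), for bulge cells in the upper panel and interfollicular epidermis in the lower one. In the bulge the groups lie close together, with Bhlhe41 and Nfil3 higher in clock-positive cells; in epidermis Nr1d1, Per3 and Nr1d2 are lower and Cry1 and Nfil3 higher in the KO.

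The second comparison asks what loss of Bmal1 changes in the epidermis of mice 1 year old. Arntl itself was read by a single probe set, with values of 9.27, 9.47 and 9.34 in wild-type arrays 1 to 3 and 9.85, 9.60 and 9.55 in KO arrays 1 to 3. The KO was 0.30 ± 0.12 higher (adjusted p = 0.530). Where this probe set lies relative to the deleted part of the gene was not analysed here, so it does not check the genotype labels. Genes that BMAL1 is known to drive differed between the genotypes instead. Nr1d1, a nuclear receptor that represses Arntl, was 15.8-fold lower in the KO (log2 change −3.98 ± 0.12 SE, n = 3 per group, adjusted p = 1.08e-05), from a mean of 12.47 ± 0.16 (SD) to 8.49 ± 0.12. Per3 fell by 2.69 ± 0.11, Nr1d2 fell by 2.22 ± 0.11 and Ciart, a repressor of the clock activators, fell by 1.90 ± 0.25, with its second probe set at −2.11. Cry1, a repressor that NR1D1 holds down, rose by 1.80 ± 0.10 and Nfil3 by 2.17 ± 0.29.

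Of 13 clock repressors and outputs tested 4 fell and 1 rose, and with adjustment over the list alone 9 fell and 1 rose (camera adjusted p = 6.81e-14, and adjusted p = 0.712 with an estimated correlation). Over all genes 3 fell after median centring and 7 after quantile normalization or cyclic loess, with 1 higher in each. After cyclic loess the list passed with an estimated correlation too (adjusted p = 0.0464). It was also the only list of 37 to pass fry (adjusted p = 0.0362). Dbp at −1.83 ± 0.29 (adjusted p = 0.0663) and Tef at −0.94 ± 0.14 (adjusted p = 0.0604) missed the threshold over all genes and passed without wild-type array 1 (adjusted p = 0.00650 and 0.0298). Bhlhe40 was at −0.98 ± 0.20 (adjusted p = 0.146), Per2 at −0.53 ± 0.16, Per1 at −0.51 ± 0.33 and Hlf at −0.42 ± 0.12, none past it. Bhlhe41 lay below the filter on dim genes, and was at −2.73 ± 0.19 when the filter was left out (adjusted p = 0.00366). The activator list also stood above other genes through Nfil3, the 1 of its 6 members that passed (0 passed after median centring), with camera adjusted p = 0.0353, and adjusted p = 0.712 with an estimated correlation. It missed the threshold without wild-type array 3 (adjusted p = 0.167), KO array 1 (0.0723) or KO array 3 (0.0646), and after quantile normalization (0.0985) or cyclic loess (0.137), and with no filter on dim genes (0.0683).

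Outside the clock, few genes passed. Serpina3b, a protease inhibitor, was 6.72-fold higher in the KO (2.75 ± 0.17), Ttc9 rose by 2.05 ± 0.25, Il18r1, a chain of the interleukin 18 receptor, by 1.93 ± 0.15, Abhd12b by 1.84 ± 0.23 and the surface glycoprotein Thy1 by 1.19 ± 0.12. Serpina4-ps1, Chn2 and Marcks rose by 1.09, 0.99 and 0.83. Lrrn3 fell by 1.24 ± 0.13, with the cation channel gene Trpm3 and the scaffold gene Homer2 at −1.15, Klf12 at −1.11, and Nlrp1c-ps and Fam171b at −1.08. In all 27 of 13956 genes passed, 11 higher and 16 lower, against 1111 at an unadjusted p under 0.05, and 18 passed with the same sign under all 4 scalings. The epidermis arrays spread widely within groups: their first principal component held 48.2% of the variance and did not part the genotypes, while the second held 30.9% and parted them in all 6 arrays.

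Several lists moved with camera while few or none of their members passed alone. Cell cycle genes stood higher in the KO, with 0 of 37 past the threshold over all genes and 12 when adjusted over the list alone (adjusted p = 5.52e-08, and adjusted p = 0.712 with an estimated correlation); Cdk1 was at 0.61 ± 0.12 and Aurkb at 0.68 ± 0.14. Wild-type array 3 (list mean −0.250 relative to the 6 arrays) and KO array 1 (0.285) stood furthest apart. KO array 2 (−0.0232) lay close to wild-type arrays 1 and 2 (−0.0447 and −0.0314). Oxidative phosphorylation genes (0 of 40 past the threshold, list median 0.12) gave an adjusted p of 3.75e-05, and an adjusted p of 0.819 with an estimated correlation. That shift lay mostly in wild-type array 1 (list mean −0.246) and KO array 1 (0.146), while the other arrays of the genotypes overlapped. CDK inhibitors and p53 targets (0 of 18, with Cdkn2c at 0.34 ± 0.12) gave an adjusted p of 0.00345, and an adjusted p of 0.751 with an estimated correlation. The same pair of arrays stood apart (−0.251 and 0.214), and KO array 3 (−0.0729) lay below wild-type arrays 2 and 3. Cytokine genes (0 of 19, and 3 adjusted over the list alone, with the chemokine Cxcl14 at 0.78 ± 0.12) gave an adjusted p of 0.0104, and an adjusted p of 0.712 with an estimated correlation, and missed without wild-type array 2 (0.0747) or KO array 3 (0.0964) and with no filter on dim genes (0.0963). Immediate early genes (0 of 29, and 1 adjusted over the list alone, with Ccn1 at 0.49 ± 0.10) gave an adjusted p of 0.0129, and an adjusted p of 0.827 with an estimated correlation, and missed without wild-type array 1 (0.174) or KO array 2 (0.162) and after cyclic loess (0.0505). Epidermal differentiation genes stood lower in the KO (0 of 28, with Flg2 at −1.38 ± 0.41, adjusted p = 3.75e-05, and adjusted p = 0.712 with an estimated correlation), but missed without KO array 1 (0.101). Their shift rested on wild-type arrays 2 and 3 (list means 0.299 and 0.479), while wild-type array 1 (−0.227) lay below KO arrays 1 and 2 (−0.172 and −0.0934).

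T cell markers also stood lower in the KO, with 0 of 6 past the threshold over all genes and 6 when adjusted over the list alone (adjusted p = 6.01e-08, and adjusted p = 0.712 with an estimated correlation). Cd3g was at −2.66 ± 0.42 (adjusted p = 0.0663) and Cd3e at −1.33 ± 0.29. Without wild-type array 1 Cd3g passed (adjusted p = 1.09e-05), but that array lay nearest to the KO, so leaving it out favours a call. In wild-type arrays 1 to 3 Cd3g read 8.53, 10.25 and 10.32, and in the KO arrays it lay between 6.96 and 7.12. Markers of Langerhans and other myeloid cells stood lower as well (0 of 8, with H2-Ab1 at −1.79 ± 0.58 and Cd74 at −1.55 ± 0.56, adjusted p = 9.17e-04, and adjusted p = 0.712 with an estimated correlation), and missed without KO array 1 (0.0902). These rested on wild-type arrays 2 and 3: H2-Ab1 read 10.34 and 10.87 there, 8.40 in wild-type array 1 and 7.44 to 8.42 in the KO. In all 10 of 37 lists passed camera and 0 passed with an estimated correlation, where the lowest adjusted p was 0.712; after cyclic loess 8 and 1 did, the 1 being the clock repressor list.

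The count of 27 genes rested on few arrays: 98 passed without wild-type array 1, 16 without wild-type array 3 or KO array 1, 8 without wild-type array 2 or KO array 3 and 7 without KO array 2. Of the 20 genes named with the largest changes, Nr1d1, Per3, Nr1d2, Cry1, Serpina3b and Il18r1 kept their call without any 1 array, and the other 14 lost it without KO array 2 (adjusted p from 0.0985 to 0.205), 13 of them without KO array 3, 11 without wild-type array 2, 9 without KO array 1 and 5 without wild-type array 3 (adjusted p from 0.0524 to 0.197 over these).

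**Figure D2:**
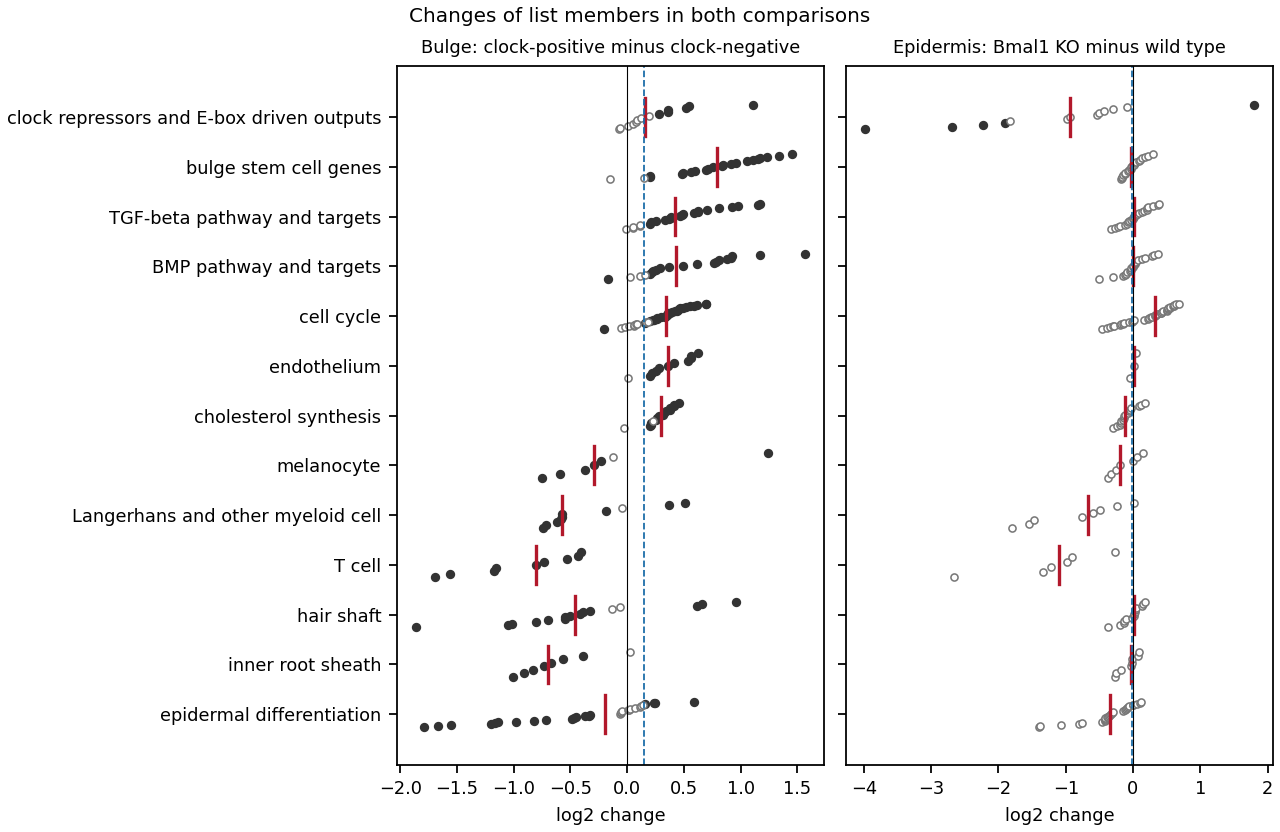
Log2 change of each tested member of 13 lists in the bulge (left, clock-positive minus clock-negative) and in epidermis (right, Bmal1 KO minus wild type). Filled points passed the threshold, open points did not, red bars mark list medians and the dashed line the median of all genes. In the bulge, 20 of 22 bulge stem cell genes and 0 of 9 T cell genes are filled points to the right; in epidermis the filled points all belong to the clock list.

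**Figure D3:**
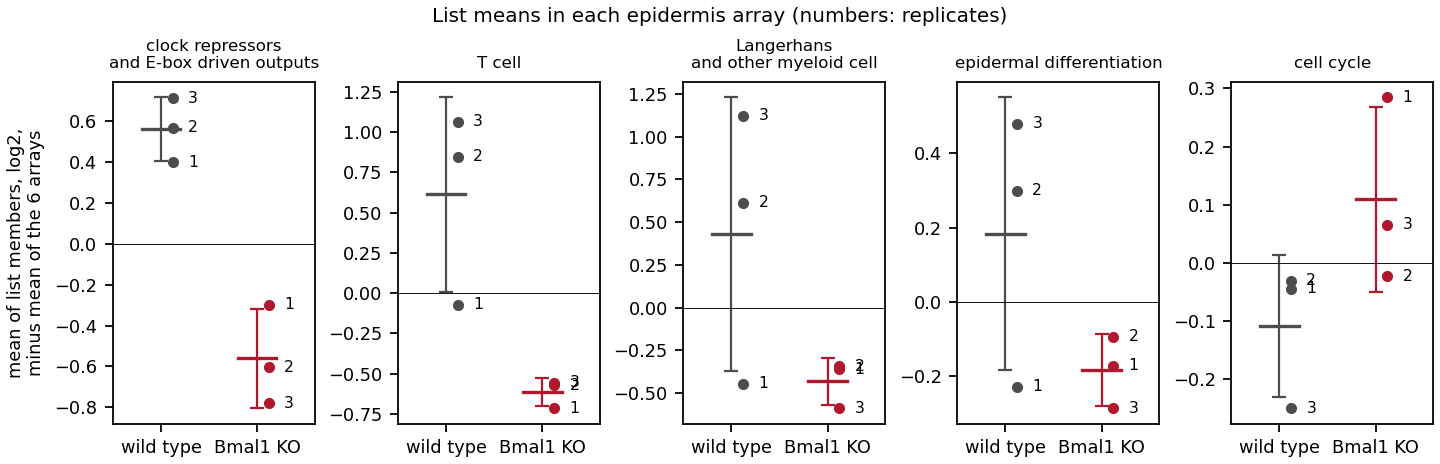
Mean of the members of 5 lists in each epidermis array, as log2 deviation from the mean of the 6 arrays, with replicate numbers beside the points and the mean and SD of 3 arrays per group as bars. The clock list parts the genotypes in all 6 arrays, whereas wild-type array 1 lies near the KO arrays for the myeloid and epidermal differentiation lists.

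The third comparison asks whether the contrast between clock-positive and clock-negative bulge cells resembles that between wild-type and KO epidermis, each taken from the group with the more active clock by label to the other. The sets also differ in tissue, age and pool size, and in the levels of sex-linked genes. Clock genes differed between the contrasts in size or in direction, 13 of 19 in all. Ciart (0.36 in the bulge and 1.90 in epidermis), Dbp and Tef, for example, went the same way in both and differed in size. Bhlhe41, higher in clock-positive cells and in wild-type epidermis, was not among the 19. Nr1d1 was 0.08 higher in clock-positive bulge cells and 3.98 higher in wild-type epidermis, a difference of −3.91 ± 0.14 (adjusted p = 1.32e-09), and for Per3 the difference was −2.76 ± 0.13 and for Nr1d2 −2.14 ± 0.13. Nfil3 was 1.01 higher in clock-positive bulge cells and lower in wild-type epidermis (−2.17), a difference of 3.18 ± 0.33 (adjusted p = 5.33e-05). Cd3g fell in clock-positive cells (−1.69) and was higher in wild-type epidermis (2.66), a difference of −4.34 ± 0.47 (adjusted p = 6.22e-05). Nkg7, a gene of cytotoxic lymphocytes, differed by −3.02 ± 0.33 and Flg2, a filaggrin-like protein of the cornified layer, by −2.93 ± 0.45.

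Of 13956 genes 2422 differed, 1518 higher and 904 lower, and 1643 did so with the same sign under all 4 scalings. With no filter on dim genes 1373 were higher and 1129 lower, and with the lowest 50% of genes left out 1267 and 328. Median centring gave 2751 higher and 431 lower, quantile normalization 1822 and 1184, and cyclic loess 1744 and 1023. The count fell to 1210, 1455 and 1265 without clock-positive array 1, 2 or 3, to 1189 and 1310 without clock-negative array 2 or 3 and to 1499 without KO array 2, and rose to 4208 without KO array 3. Lists that differed with camera numbered 17 of 37, and 0 did with an estimated correlation (lowest adjusted p = 0.185). Bulge stem cell genes (15 of 22 higher, adjusted p = 4.39e-08, and adjusted p = 0.219 with an estimated correlation) and cell cycle genes (21 of 37 higher, adjusted p = 1.90e-05, and adjusted p = 0.519 with an estimated correlation) lay on the clock-positive side. T cell genes (8 of 8 lower, adjusted p = 3.04e-10, and adjusted p = 0.219 with an estimated correlation) and clock repressors (8 of 13 lower and 1 higher, adjusted p = 2.38e-06, and adjusted p = 0.398 with an estimated correlation) lay on the other.

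Of the genes called in both contrasts, 7 were higher in both clock-positive bulge cells and wild-type epidermis, where 7.02 would fall together at random (two-sided Fisher's exact test, p = 1): Cdc25b, a phosphatase of the cell cycle, Ciart, Fam171b, Homer2, Lrrn3, Sncg and Trpm3. Of these Lrrn3 changed by 1.48 ± 0.09 in the bulge and 1.24 ± 0.13 in epidermis, Fam171b by 1.53 ± 0.10 and 1.08 ± 0.14, and Sncg by 0.99 ± 0.06 and 1.06 ± 0.13. Serpina3b and Thy1 were lower in both (2 against 1.51, two-sided Fisher's exact test, p = 0.652). Marcks, Nfil3 and Rras2 were higher in clock-positive cells and lower in wild-type epidermis (3 against 4.21, p = 0.516 in Fisher's exact test), though Rras2 changed sign in the bulge under quantile normalization and cyclic loess, and Rsad1 was the reverse (1 against 2.51, p = 0.491). Across 13100 genes the contrasts had a Pearson r of −0.131 and a Spearman rho of −0.150; genes are not independent replicates, and 81 of 100 relabellings of the arrays gave an r as far from 0. The sign of r turned without wild-type array 1 (0.0219) or KO array 1 (0.0921) and with no filter on dim genes (0.00450).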

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

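The test of whether every other cell type rises alike and the count with the bulge labels held were set only after the results were seen, and cyclic loess and the second T cell list were chosen after the data were seen, the list before its own result. The 5 genes and the count that differ between the 2 contrasts stand out by the test of the difference itself. Cd3g differed by −4.34, Nr1d1 by −3.91, Nfil3 by 3.18, Nkg7 by −3.02 and Flg2 by −2.93 on the log2 scale. In all 2422 genes differed; 4 of 100 relabellings of the arrays within both comparisons gave as many, the real one included, and the highest other gave 8669. That share restates the bulge contrast, as all 4 are among the 12 drawn with the real bulge labels, and with other bulge labels the highest was 19. With the real bulge labels held, 6 of the 20 ways to label the epidermis arrays gave as many genes, so chance cannot be excluded for the part of the count that depends on genotype. Signals in probe sets without 1 gene symbol, which no comparison used, passed the threshold in 3776 of 7508 tested in the bulge (1097 higher and 2679 lower in clock-positive cells) and in 8 of 4430 in epidermis (2 higher and 6 lower in the KO). These counts are given as deposited only. Among the genes tested in the bulge the change rose with the mean level (r = 0.366, and 0.00817 after cyclic loess). The balance of 1097 and 2679 may therefore partly reflect the range of the arrays, which was not tested for these probe sets.

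For the counts of the first 2 comparisons the splits are too few for a share under 0.05. In the bulge 1 of the 10 splits of 6 arrays into 3 and 3, the real one, gave 8866 genes, and the highest other gave 0. In epidermis 2 of 10 splits gave at least the real count of 27, and the other one gave 86: wild-type array 1 with KO arrays 2 and 3 against the rest, which points to a structure of these arrays apart from genotype. This split follows the SD of the arrays, which was 2.00 to 2.06 in wild-type array 1 and KO arrays 2 and 3 and 2.10 to 2.14 in the rest. For the correlation of the contrasts 81 of 100 relabellings gave an r as far from 0 as −0.131, up to 0.549, so chance cannot be excluded.

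A first pattern is that bulge genes were higher in the clock-positive sort and genes of T cells and of differentiated keratinocytes in the clock-negative sort. The clock-negative arrays have a narrower range of values (SD 1.88 to 1.91, against 2.00 to 2.02), but after cyclic loess, which removes trends with intensity, bulge stem cell genes still stood 0.546 above all genes and T cell markers at −0.833 relative to them, which argues against the range of the arrays as the whole cause, though neither list passed camera with an estimated correlation then (adjusted p = 0.101 and 0.0860). Markers of other types did not all move alike: 10 of 11 endothelium markers were higher in clock-positive cells and 0 lower (8 and 0 after cyclic loess), while all 9 T cell markers were lower. The comparison was set after these values were known. It is therefore no independent test of a lower share of bulge cells that raises all other types alike. Whether the endothelium markers came from endothelial cells was not tested. Endothelium was the 1 marker list of another type to pass camera on that side in both scalings, and that call was lost with an estimated correlation (0.242) and with the lowest 50% of genes left out (0.136). These values do not speak against a lower share of bulge cells that raises only some other types, which stays open. T cells among the clock-negative cells are a candidate source of the T cell signal: in a second list of 35 T cell and lymphocyte genes, 12 of 16 tested were higher in all 3 clock-negative arrays (75%, against 19.1% of all genes), with Cd3g at 9.19 and Cd7 at 9.52 there, although a gate on alpha6 integrin and CD34 should leave T cells out. A gene can pass the filter on dim genes through the arrays where it is high, so the share of 75% may be raised. The difference in Venus reporter that the design names stays open as an untested biological explanation for the keratinocyte genes, beside the position of cells in the follicle, which no value here decides.

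Another pattern is the lower T cell signal in KO epidermis, where all 3 KO arrays lay below all 3 wild-type arrays for 5 of 6 markers. Cyclic loess left the list median at −1.07 (camera adjusted p = 6.78e-06), which argues against unequal range of the arrays as its whole cause, though with an estimated correlation the list passed neither before (0.712) nor after it (0.672). Fewer T cells among the sorted KO cells cannot be told apart from other explanations: in the second list 6 of 16 genes tested, of 35 listed, were lower in all 3 KO arrays (37.5%, against 8.56% of all genes), between the shares set beforehand for and against it. Here too a gene can pass the filter on dim genes through the arrays where it is high, so the share of 37.5% may be raised. Wild-type array 1 lay nearest to the KO arrays (Cd3g 8.53). Thy1, a surface protein of fibroblasts and T cells, went the other way and rose in the KO (1.19 ± 0.12, adjusted p = 0.0155). A change of resident T cells with genotype stays among the open explanations, as untested.

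A last pattern is the spread within the groups of epidermis arrays, of which 69.0% lay on a single axis. Cyclic loess removed 59.1% of the variance on that axis but 30.8% of all variance within the groups, so unequal range of the arrays may account for more than not of that axis, and for less of the spread as a whole. The array SD ran from 2.02 to 2.11 in wild type and from 2.00 to 2.14 in the KO, and the remainder was not explained. No biological explanation was tested for it.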

How the results depend on the processing

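Cyclic loess, the array SD as a covariate and median centring of the lists were chosen after the data were seen. In the bulge the count of 8866 became 1008 with a fold of at least 1.5, 5443 after quantile normalization, 5739 after cyclic loess and 5301 with all 12 arrays in 1 fit; it stayed within 1.5 times under the other alternatives, from 7132 to 9805 without 1 array. In epidermis the count of 27 became 65 at an adjusted p under 0.10, 16 with no filter and 47 with a 50% filter on dim genes, 80 after quantile normalization, 85 after cyclic loess, 57 with an intensity trend, 56 with a robust trend, 407 with all 12 arrays in 1 fit, 279 with the array SD as a covariate, and 7 to 98 without 1 array. Array weights gave 6694, from an estimate of the weights that did not converge. For the difference the count of 2422 became 1455 with a fold of at least 1.5, 4270 at an adjusted p under 0.10, 1595 with a 50% filter, 9916 with array weights, and 1189 to 4208 without 1 array. A stricter fold, p or filter changes the count by construction; for the rest the cause was not tested. Same-numbered samples were not treated as pairs. Deviations of same-numbered arrays correlated at 0.241, 0.260 and −0.0610 in the bulge and at −0.442, 0.0427 and −0.525 in epidermis. The highest value for differently numbered arrays was 0.126 in the bulge and 0.538 in epidermis, so pairing stays undecided in the bulge. A block for replicate number, planned before these values were known, gave 9351, 3 and 687 genes. The correlation of −0.131 between the contrasts reversed with no filter (0.00450) and ranged from −0.315 to 0.0921 without 1 array, where it reversed without wild-type array 1 (0.0219) and KO array 1 (0.0921).

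Signs turned for few named genes. In the bulge Hlf went to −0.22 under quantile normalization and −0.22 under cyclic loess, Arntl to −0.0355 and −0.0482, and Rras2 to −0.0341 and −0.0420. Under cyclic loess alone Fasn went to −0.0105, Plet1 to −0.00052 and Pmp22 to −0.0101. In epidermis Krt25 went to 0.22 with array weights. The interfollicular basal cell list in the bulge turned upward in fry (adjusted p = 0.00422), which does not compare it with other genes. For these the cause was not tested. Of the other values of named genes, 3439 in the bulge, 3205 in epidermis and 737 for the difference kept direction and side of the threshold, 36, 222 and 21 came past it, and 237, 112 and 64 fell short of it. Of list values 557 in the bulge and 542 in epidermis kept both, 38 and 12 came past the threshold, and 24 and 33 fell short, 13 and 10 of these with an estimated correlation. Signal over background limits dim genes: no detection calls were used, and the filter was set on means alone.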

Other observations

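Beyond the lists described, hormone and stress genes also moved in the bulge sorts, though not beyond other genes once dim genes were filtered. With no filter, glucocorticoid responsive (camera adjusted p = 0.0428), immediate early (0.00253) and Notch genes (0.0428) did pass camera. As the change rose with the mean level (r = 0.366), these passes may reflect the dim genes added. The values that follow are with the filter and as deposited unless said otherwise. Of 12 glucocorticoid responsive genes 7 rose and 0 fell in clock-positive cells, among them the receptor Nr3c1 at 0.77 ± 0.07, Sgk1 at 0.75 ± 0.07 and the chaperone partner Fkbp5 at 0.62 ± 0.06 (camera adjusted p = 0.0889). Of 29 immediate early genes 17 rose and 2 fell, with Ier3 at 1.10 ± 0.08 and Jun at 0.64 ± 0.07 (camera adjusted p = 0.124). Among antioxidant and NRF2 targets 10 of 21 rose and 1 fell, led by Nqo1 at 1.13 ± 0.06 (camera adjusted p = 0.274). Hair germ and activated progenitor genes rose in 10 of 16 and fell in 3, with Gli2, an effector of hedgehog signals, at 0.87 ± 0.07 (camera adjusted p = 0.261). Wnt inhibitors rose in 7 of 16 and fell in 2, with Dkk3 at 1.30 ± 0.06 (camera adjusted p = 0.768), and Wnt targets rose in 5 of 14 and fell in 1, with Lef1 at 0.66 ± 0.07 (camera adjusted p = 0.865). The balance of Wnt targets depended on the scaling, with 5 higher and 4 lower after quantile normalization, 4 and 5 after cyclic loess and 8 and 0 after median centring. In the Notch list 8 of 15 rose and 2 fell, with Lfng at 0.79 ± 0.06 (camera adjusted p = 0.297). After cyclic loess 4 Notch genes rose and 3 fell, 9 immediate early genes rose and 4 fell, 5 glucocorticoid responsive genes rose and 1 fell, and 7 antioxidant genes rose and 3 fell. All of these lists passed fry in the bulge as deposited, where 32 of 39 lists did. After cyclic loess Wnt targets (fry adjusted p = 0.0755) and Notch genes (0.0831) no longer passed it.

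Other gene lists in the bulge were, by camera with the filter, not past the threshold as deposited. With no filter on dim genes, oxidative phosphorylation (5.31e-04), basal keratinocyte (0.00188), CDK inhibitor (0.00331), DNA repair (0.00363), chaperone (0.0267) and mast cell genes (0.0180) passed. For the lists that rose, these passes may likewise reflect the dim genes added. Mast cell genes also passed with the mean of all probe sets (0.0475), with all 12 arrays in 1 fit (0.0410) and without clock-negative array 1 (0.0277), and basal keratinocyte genes with all 12 arrays in 1 fit (0.0440). Cytokine genes passed with the mean of all probe sets (0.0378) and without clock-positive array 1 (0.0431) or clock-negative array 2 (0.0405). The values that follow are with the filter and as deposited unless said otherwise. Basal keratinocyte genes rose in 12 of 18 (adjusted p = 0.0631), CDK inhibitors and p53 targets in 10 of 18 (0.0889), oxidative phosphorylation genes in 24 of 40 (0.0636), DNA repair genes in 16 of 30 (0.208), stress chaperones in 10 of 22 (0.346) and ribosomal proteins in 6 of 37 (0.958), with 0 lower in each. These counts depended on the scaling. After quantile normalization 4 oxidative phosphorylation genes rose and 0 fell, 6 DNA repair genes rose and 0 fell, and 1 chaperone gene rose and 2 fell. After cyclic loess these were 2 and 1, 6 and 1, and 1 and 3, with basal keratinocyte genes at 9 and 2 and CDK inhibitors at 6 and 0. After median centring more rose, such as 36 oxidative phosphorylation and 28 ribosomal protein genes. Adjusted over the list alone, 18 immediate early, 14 DNA repair, 9 chaperone and 2 ribosomal protein genes rose, as did 2 of the clock activators. Rpl38 was read by 4 probe sets that disagree in sign. Interferon response genes rose in 3 of 17 and fell in 4 (0.224), with a median of 0.0080 and a mean of −0.0259, and cytokine genes rose in 2 of 17 and fell in 6 (0.0636). Of the interferon genes 8 rose and 3 fell after median centring, and 0 rose and 4 fell after cyclic loess. Of the cytokine genes 5 rose and 3 fell, and 3 rose and 4 fell, in turn. Of the marker lists, mast cell genes fell in 2 of 3 (0.0503), adipocyte genes rose in 1 of 6 and fell in 3 (0.0812), sebocyte genes rose in 4 of 7 (0.503), pericyte genes in 2 of 4 (0.958) and Y-linked genes in 2 of 3 (0.522). Schwann cell genes rose in 1 of 5 and fell in 2 (0.297), with a median of 0.0043 and a mean of −0.0393. Dermal fibroblast genes rose in 4 of 12 and fell in 5 (0.311), and upper hair follicle genes rose in 3 of 11 and fell in 3 (0.297), both with a median below 0 and a mean above it. The upper hair follicle list stood below other genes after quantile normalization (0.0476) and cyclic loess (0.0404), with 1 higher and 6 lower in each, and with the lowest 50% of genes left out (0.0169), but not after cyclic loess with an estimated correlation (0.386). Interfollicular basal cell genes rose in 2 of 8 and fell in 0 (0.752), with a mean of 0.135, and after cyclic loess 2 rose and 3 fell. The red blood cell and X inactivation lists had fewer than 3 genes and were not tested.

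In epidermis the lists not named before did not pass camera as deposited with the 30% filter. With the lowest 50% of genes left out, dermal fibroblast (adjusted p = 0.0173), interferon response (0.0341) and melanocyte genes (0.0386) passed. Without wild-type array 1, dermal fibroblast (0.0496), upper hair follicle (0.00322) and interfollicular basal cell genes (0.0363) passed, and without wild-type array 3 interferon response genes (0.0167). Without KO array 1, interferon response (0.0311), cholesterol synthesis (0.0409), DNA repair (0.0409), dermal fibroblast (0.0222) and pericyte genes (0.0371) passed. Those higher in the KO by direction were bulge stem cell genes (adjusted p = 0.800), hair germ genes (0.147), Wnt inhibitors (0.860), TGF-beta (0.331), BMP (0.826) and Notch genes (0.966), basal keratinocyte genes (0.473), antioxidant genes (0.157), interferon response genes (0.0984), glucocorticoid responsive genes (0.473), ribosomal proteins (0.274) and stress chaperones (0.208). Wnt targets (0.275), cholesterol synthesis (0.191) and DNA repair genes (0.428) lay lower. Of the marker lists, dermal fibroblast (0.132), endothelium (0.860), skeletal muscle (0.473), adipocyte (0.911), sebocyte (0.473), interfollicular basal cell (0.0859) and pericyte genes (0.147) lay higher, and melanocyte (0.292), inner root sheath (0.771), hair shaft (0.966), upper hair follicle (0.274) and Schwann cell genes (0.157) lower. For bulge stem cell, Wnt inhibitor, Notch, adipocyte and hair shaft genes the median, the mean and the test differed in sign, and BMP genes lay lower in fry. Adjusted over the list alone, 3 fibroblast genes rose and 1 fell, 1 pericyte gene rose and 1 Schwann cell gene fell. Members past the threshold were Thy1 in the fibroblast list and Cry1, which the DNA repair list also holds. Mast cell and Y-linked genes had fewer than 3 tested. In the test of the difference between the contrasts, hair germ (0.0249), CDK inhibitor (0.00677), basal keratinocyte (0.0320), immediate early (0.0206) and oxidative phosphorylation genes (9.13e-04), TGF-beta (1.90e-05), BMP (0.00198) and endothelium genes (0.00838) lay on the clock-positive side. Epidermal differentiation (1.23e-08), melanocyte (0.00782), myeloid (0.00129), inner root sheath (2.77e-05) and hair shaft genes (5.06e-04) lay on the other, and none of these passed with an estimated correlation.

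Thy1, a surface protein of fibroblasts and T cells, was higher in each KO array (12.12 to 12.37) than in any wild-type array (10.88 to 11.20), while the T cell markers were lower there. Sex-linked genes differed mostly between the sets of arrays. Within the bulge set Eif2s3y was 0.34 ± 0.09 and Uty 0.27 ± 0.10 higher in clock-positive cells. Xist read 4.64 to 5.02 in the 6 bulge arrays and 11.97 to 12.77 in the 6 epidermis arrays. Eif2s3y read 7.36 to 7.93 in bulge and 4.27 to 4.35 in epidermis, Kdm5d 7.93 to 8.09 and 5.13 to 5.31, and Uty 7.14 to 7.76 and 4.64 to 4.89. The sets appear to have been normalized separately, so these levels are not tested against each other.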
